A study of Mus musculus with 36 samples.

How the data were processed

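Transcripts were measured by RNA sequencing in 36 libraries from bone marrow cells of C57BL/6 mice, 12 groups of 3 biological replicates. The groups were haematopoietic stem cells (HSC) and granulocyte-macrophage progenitors (GMP), each cultured with or without TNFα for 3 h or 12 h, or sorted from mice 3 h after an injection of TNFα or PBS. Cultured cells were sorted before exposure, and injected mice were exposed before their cells were sorted. Per the labels, RNA was amplified with a whole-transcriptome kit before library construction, so reads are not independent molecules, and every interval and detection floor given here covers counting error only.

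The deposited values are signal, gene counts divided by a size factor per library and rounded to 1 decimal, in 1 file per library with 43432 genes each. The submitters' processing notes name CASAVA 1.8.2, STAR, DESeq2 and the builds GRCm38 and mm10 without their settings. Neither the counting tool, the annotation release nor the use of strand is stated, so reads from overlapping or antisense genes and from close paralogs (the Bcl2a1, Serpina3, H2-Q and Ifit families) may be counted for either gene. The values of each library lay on whole multiples of 1 step, with 99.98 to 100 percent of the values above 0 within 0.05 of a multiple, and 1 read was worth 0.71 to 1.71 units. Whole reads were recovered on that basis and gave 7.06 to 16.96 M reads per library (median 12.84 M), of which 24.29 to 40.49 percent were mitochondrial ribosomal RNA. Between 15768 and 18488 genes were above 0 in a library, and 10960 in all of them. Coordinates are from GENCODE for GRCm38, which matched 42462 of the gene identifiers, and gene symbols are those of the files.

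Values were analysed as log2(value + 1) with limma-trend (limma 3.58.1 in R 4.3.3, robust fitting off) in 1 model of all 36 libraries with a mean per group, which left 24 residual degrees of freedom. Genes with a value of at least 5 in at least 3 libraries were tested, 17302 of 43432. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with each comparison adjusted on its own. The analysis planned edgeR for raw counts and this limma model for depth-normalised values; the second applied. The main model was fixed beforehand without the replicate numbers as pairs, and no label says that they link libraries. Correlations between libraries of 1 number were under 0.1 in 12 of 18 cases but the best of the 3 numbers in 17. Sex-linked genes also linked the cultured libraries numbered 1. Fits with replicate as a block and without those libraries are among the alternatives. There were 14 comparisons, namely TNFα against control for each cell type and setting (6), the difference of those effects between HSC and GMP (3), between times or routes within a cell type (4), and HSC against GMP in PBS-injected mice (1). Differences of effects were tested as interaction terms. Control groups were also compared across culture times and between culture and PBS injection, for description.

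The model pools the spread of all groups, which was not equal: the residual SD of a group ranged from 0.696 to 0.863 in HSC and from 0.517 to 0.741 in GMP. Tested on simulated data (16664 genes, spread taken from the libraries, 3 against 3), the limma model recovered 91 to 98 percent of 4-fold and 51 to 66 percent of 2-fold changes, and 7.3 to 22.2 percent of its calls were false, the most in cultured HSC at 3 h. On the same simulated data edgeR made 3.5 to 7.4 percent false calls, DESeq2 9.1 to 14 percent and limma within 1 cell type 6.7 to 14.9 percent. The shares for limma lie above the 5 percent that the threshold aims for, so a call in HSC that stands near the threshold is less certain than its adjusted p states. Simulated changes were set only in genes well above the low-value filter, so recovery among low genes was not tested. Each gene had the same spread in every group and libraries were independent, so unequal spread and a shared origin of libraries were not tested either.

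A panel of 25 genes and 33 gene lists were fixed before the data were examined, as were the comparisons, tests, threshold and the rule for named genes. The lists were NF-κB targets, cytokines and chemokines, anti-apoptotic genes, pro-apoptotic genes, necroptosis and complex II, TNF receptor signalling, interferon response, antigen presentation, immediate early and stress genes, S phase, G2/M phase, CDK inhibitors and quiescence, p53 targets, HSC identity, GMP granule genes, myeloid regulators, and markers of mature neutrophils, monocytes and macrophages, dendritic cells, megakaryocytes, erythroid cells, B cells, T and NK cells, basophils, mast cells and eosinophils, and stroma and endothelium. The rest were the unfolded protein response, cholesterol synthesis, glycolysis, oxidative phosphorylation, antioxidant genes, ribosomal proteins, mitochondrially encoded genes and sex-linked genes. Each list was tested with camera (limma) against all other genes, with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over 462 tests for the 14 comparisons and separately for the control comparisons. The plan named log2 counts per M reads for camera, but it was run on log2(value + 1), the scale of the model. Counts of list members are given over all genes tested and adjusted over the list alone. Lists share members, so their results are not independent. Traf1 is both an NF-κB target and an anti-apoptotic gene, and Sod2 both an NF-κB target and an antioxidant gene. Birc3 and Tnfaip3 are in the anti-apoptotic and the necroptosis lists. All adjusted p values are from limma, and those of lists from camera.

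Named genes are the panel, the 5 largest rises and falls by fold change in each comparison (10 for the HSC and GMP controls), up to 4 members with the smallest p in each list, and the genes of the sort. The fold-change rule took called genes with a mean of at least 5 counts per M reads, all 3 treated libraries on 1 side of all 3 controls, and no predicted genes or pseudogenes. Where every library of a group was at 0, a fold is a lower bound computed with 3 reads per library for that group. Where a group held 1 to 3 reads, the ratio is given with its exact 95 percent interval. Alternatives were no low-value filter, pseudocounts of 0.5 and 5, DESeq2 size factors in edgeR 4.0.16, DESeq2 1.42.0, the replicate number as a block, only the libraries of a comparison, and leaving out each library in turn. Alternatives chosen after the data were seen were edgeR with TMM scaling, TMM-scaled values in limma, the 18 libraries of 1 cell type, and leaving out the cultured libraries numbered 1, which differ in sex-linked genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No library was left out of the main results.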

Results

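RNA was sequenced from 2 cell types of mouse bone marrow. HSC were stem cells sorted for Kit, Sca-1 and CD150 and against lineage markers, Flk2 and CD48. GMP, progenitors of granulocytes and macrophages, were sorted for Kit, Fcγ receptor and CD34 and against Sca-1. Each cell type had 6 groups of 3 libraries. Of these, 4 were cultures with or without 1 µg/ml TNFα, an inflammatory cytokine, for 3 h or 12 h. The other 2 were sorted 3 h after mice received 2 µg TNFα or PBS. Labels of the cultured HSC name both settings, and these libraries were taken as cultured because their titles open with ex and their treatment labels with ex vivo. Libraries held 7.06 to 16.96 M reads. Values are normalised read counts, given as mean ± SD with n = 3 in every group, the TNFα group first. Changes are log2 differences of the fitted group means and stand in parentheses after a gene where no unit is named.

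**Figure D1:**
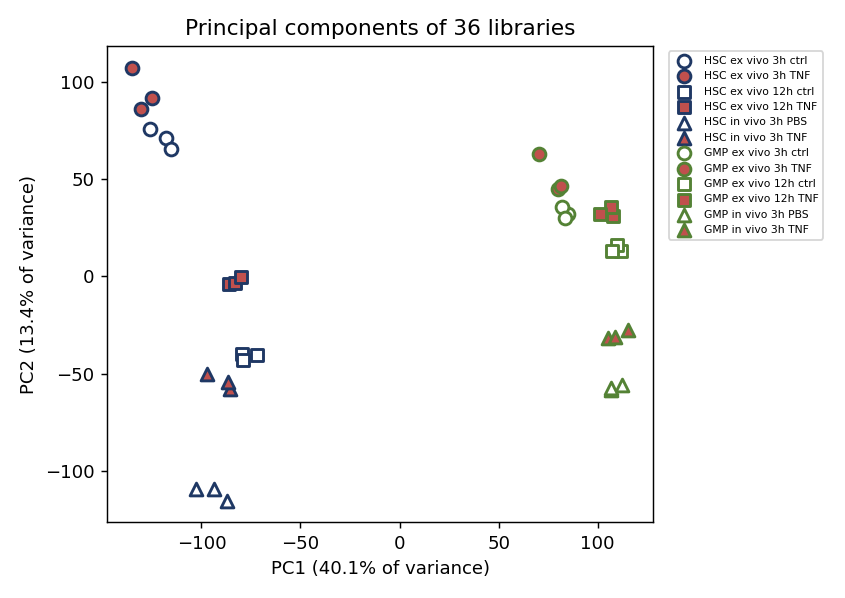
Scores of the 36 libraries on the first 2 principal components of log2(value + 1). Each point is a library. The outline gives the cell type, the shape the setting, and a filled point TNFα. PC1 holds 40.1 percent and PC2 13.4 percent of the variance, and TNFα-treated libraries lie higher on PC2 than the controls of their setting.

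HSC and GMP of PBS-injected mice were compared to describe both cell types before any TNFα, with the HSC value first. HSC had more RNA of Mpl, the thrombopoietin receptor, at 12454 ± 1451 (SD, n = 3) against 19.3 ± 16.2 (ENSMUSG00000006389, chromosome 4, 118442415 to 118457513). Its log2 difference was 9.56 (adjusted p = 3.16e-22). Mpo, the peroxidase of neutrophil granules, was lower in HSC at 128 ± 57.6 (SD, n = 3) against 140030 ± 6061 (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413). Its log2 difference was -10.18 (adjusted p = 9.87e-25). The granule proteases Elane (58.3 ± 50.8 against 51288 ± 2285) and Ctsg (11.8 ± 4.27 against 14214 ± 982) were lower too. Of the genes of the sort, 4 differed in the direction of the gates. Ly6a, which encodes Sca-1, was at 1092 ± 203 against 21.7 ± 6.4, and Slamf1, which encodes CD150, at 621 ± 97 against 0.3 ± 0.52. Cd48 was at 31.5 ± 21.1 against 1374 ± 119 and the Fcγ receptor Fcgr3 at 5.57 ± 6.84 against 1216 ± 154. Kit (1.33) RNA was higher in HSC, though both cell types were sorted for it. Flt3 encodes Flk2, against which HSC were sorted, and its RNA was nevertheless higher in HSC than in GMP (2.14). Cd34 RNA differed by -0.45 (adjusted p = 0.079), which did not pass the threshold.

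Of HSC identity genes, 36 of 38 were higher (36 up and 1 down adjusted over the list alone), adjusted p = 2.07e-06 with an estimated correlation. They included the transcription factors Meis1 (4.73), Hlf (14499.9 ± 647 against 234 ± 36.9) and Pbx1 (4.23). Of megakaryocyte genes, 19 of 20 were higher (19 adjusted over the list alone), adjusted p = 0.00325 with an estimated correlation. Examples were F2r (5.62) and Vwf, von Willebrand factor (948 ± 188 against 7.93 ± 3.57). Of GMP granule genes, 31 of 32 were lower (31 adjusted over the list alone), adjusted p = 1.23e-05 with an estimated correlation. Of monocyte and macrophage markers, 4 of 18 were higher and 11 lower (4 and 11 adjusted over the list alone), adjusted p = 0.0141 with an estimated correlation. Of S phase genes, 32 of 36 were lower (32 adjusted over the list alone), adjusted p = 0.0207 with an estimated correlation, such as Rrm2, a subunit of ribonucleotide reductase (-2.53). Of G2/M genes, 34 of 36 were lower (35 adjusted over the list alone), adjusted p = 0.0499 with an estimated correlation, such as Top2a, a topoisomerase of dividing cells (4131 ± 683 against 12461 ± 764). Of interferon genes, 34 of 43 were higher and 1 lower (36 and 1 adjusted over the list alone), a list call lost at adjusted p = 0.222 with an estimated correlation. Of oxidative phosphorylation genes, 24 of 30 were lower (26 adjusted over the list alone), a list call lost at adjusted p = 0.256 with an estimated correlation. Of unfolded protein response genes, 3 of 24 were higher and 18 lower (3 and 19 adjusted over the list alone), a list call lost at adjusted p = 0.222 with an estimated correlation. Of immediate early genes, 26 of 33 were higher and 4 lower (26 and 4 adjusted over the list alone), a list call lost at adjusted p = 0.301 with an estimated correlation. Of basophil, mast cell and eosinophil markers, 2 of 14 were higher and 10 lower (3 and 10 adjusted over the list alone), a list call lost at adjusted p = 0.0901 with an estimated correlation.

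GMP had only 1 to 3 reads of several HSC genes, and ratios are given with their interval. They were 2052-fold, 568 to 16946 for Aldh1a1, 2447-fold, 439 to 96687 for Prex2 and 951-fold, 325 to 4616 for Bgn. Further ratios were 1877-fold, 337 to 74188 for Slamf1, 957-fold, 265 to 7909 for Gimap8 and 1138-fold, 315 to 9405 for Tox. Nrk was at least 189-fold and Robo4 at least 157-fold higher in HSC. Mmrn1 was higher by 9.6. Ly86 was at least 419-fold lower in HSC, and Pyhin1 lower by a ratio of 1450.1-fold, 401 to 11980. F13a1 (-10.46), Chdh (-10.44), Ly6c2 (-9.49), Atp8b4 (-9.43) and Atp1a3 (-9.37) were lower as well. In the panel, HSC had more of the CDK inhibitor Cdkn1c (6.96), Mecom (7.57), Procr (7.1), Traf1 (4.8) and Relb (3.42). They also had more Bcl2l1 (2.14), Birc2 (1.27) and Mcl1 (1.08), all inhibitors of cell death. Nfkb2 (1.1) was not called without GMP PBS 3 (adjusted p = 0.116). HSC had less Cebpa (-7.16), Mki67 (-1.46), Mlkl (-1.37), Spi1 (-1.32) and Casp8 (-0.61). limma called 7153 genes, 3977 higher and 3176 lower in HSC. The median of all genes differed by 0.116.

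The effect of TNFα on HSC after 3 h of culture included rises of NF-κB targets and cytokines. Cd83, a surface protein of mature dendritic cells, rose to 576 ± 112 (SD, n = 3) against 25.6 ± 21.3 (ENSMUSG00000015396, chromosome 13, 43784775 to 43803132). Its log2 change was 5.28 (adjusted p = 0.000362). The adhesion receptor gene Vcam1 rose to 1257 ± 331 against 80.9 ± 46.7 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688). Il1a (174 ± 132 against 12.2 ± 18.5), Il1b (179 ± 155 against 6.3 ± 2.82) and Nod2, a sensor of bacterial cell walls (142 ± 30.04 against 5.7 ± 2.52), completed the 5 largest rises. The NF-κB inhibitors Nfkbia (2393 ± 648 against 351 ± 35.7) and Tnfaip3 (2135 ± 416 against 354 ± 78.7) rose as well. The falls were smaller, with Bag2, a co-chaperone, at 62.3 ± 35 against 232 ± 55.5 and Zfp36l2, a protein of mRNA decay, at 722 ± 307 against 2702 ± 381.

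Of NF-κB targets, 31 of 50 rose (38 up and 1 down adjusted over the list alone), adjusted p = 5.04e-07 with an estimated correlation. They included Birc3, an inhibitor of cell death (2299 ± 96.9 against 594 ± 66.1), and Nfkbie (3.52). Of cytokines, 10 of 32 rose (18 up and 2 down adjusted over the list alone), adjusted p = 0.00325 with an estimated correlation, among them Ccl9 (1.99) and Cxcl10 (2.41). Of anti-apoptotic genes, 7 of 26 rose (11 adjusted over the list alone), adjusted p = 0.00931 with an estimated correlation, including Traf1, an adaptor of TNF receptors (2.33). Of interferon genes, 4 of 43 rose (4 adjusted over the list alone), a list call lost at adjusted p = 0.588 with an estimated correlation, such as the GTPases Gbp5 (2.18) and Gbp3 (1.63). Of necroptosis genes, 4 of 21 rose (5 adjusted over the list alone), a list call lost at adjusted p = 0.256 with an estimated correlation, such as the deubiquitinase Cyld (0.95). Of S phase genes, 4 of 36 fell (8 down and 1 up adjusted over the list alone), a list call lost at adjusted p = 0.301 with an estimated correlation, among them Cdt1 (-1.27). Of G2/M genes, 6 of 36 fell (11 down and 1 up adjusted over the list alone), a list call lost at adjusted p = 0.308 with an estimated correlation, among them Aurkb (-1.09). Of HSC identity genes, 4 of 38 fell (5 adjusted over the list alone), a list call lost at adjusted p = 0.328 with an estimated correlation. Hlf (-1.07) was 1 of these and was not called without control 2 or without TNFα 3 (adjusted p from 0.0984 to 0.111). Relb (3.07), Nfkb2 (2.04) and Pfkfb3, an activator of glycolysis (5493 ± 582 against 1788 ± 288), also rose.

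limma called 622 genes, 401 higher and 221 lower, with 2672 at an unadjusted p under 0.05. In other fits, given below, the count fell to as few as 43, in the 6 libraries alone. Adora3 (-2.68) was not called without control 1 (adjusted p = 0.0741). Kbtbd11 (-2.16) was not called without TNFα 1 (adjusted p = 0.0771). Rpgrip1 (-2.16) was not called without any 1 of the libraries except TNFα 3 (adjusted p from 0.05 to 0.202). Spi1 (0.91), the transcription factor PU.1, was not called without control 1 or without control 2 or without TNFα 3 (adjusted p from 0.078 to 0.126). Cflar (0.65) was not called without control 3 or without TNFα 2 (adjusted p from 0.0525 to 0.0897).

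After 12 h of culture with TNFα, cytokine and interferon-response lists were higher in HSC than in controls of the same time. Ccl22, which attracts cells bearing CCR4, rose to 6608 ± 3591 (SD, n = 3) against 30.03 ± 49.1 (ENSMUSG00000031779, chromosome 8, 94745590 to 94751699). Its log2 change was 9.7 (adjusted p = 9.77e-10). Ccl17, with the same receptor, rose to 4796 ± 4109 against 16.8 ± 11.9. Cxcl9 and Cxcl10, ligands of CXCR3, rose to 2942 ± 1979 against 6.67 ± 3.65 and 4251 ± 2475 against 41.6 ± 19.4. Ubd, a ubiquitin-like modifier, was at 163 ± 102 against 0 ± 0 and at least 71-fold higher. Bcl2a1b rose to 165 ± 51.3 against 0.5 ± 0.436 (ratio 327-fold, 90.04 to 2704). The mTOR inhibitor gene Deptor fell to 38.3 ± 4.6 against 686 ± 72.7 and Angptl2 to 91.9 ± 30.2 against 1220.2 ± 325. Fgf3 (-5.77), Cables1 (-4.03) and Chad (-3.36) were the other large falls. Flt3, a cytokine receptor of multipotent progenitors, fell to 6.03 ± 3.8 against 65 ± 17.5. Ly6a, which encodes Sca-1, rose to 6909 ± 1455 against 2066 ± 617 in these cells, which had been sorted before exposure. Kit fell by 0.9 and was not called without control 1 or without TNFα 2 (adjusted p from 0.0748 to 0.106). Cd48 fell by 2.3 and was not called without control 2 or without control 3 or without TNFα 1 (adjusted p from 0.0655 to 0.0923).

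Of interferon genes, 39 of 43 rose (42 adjusted over the list alone), adjusted p = 0.00163 with an estimated correlation. They included Gbp5 (1086 ± 258 against 104 ± 23.7), Gbp3 (2.12) and Parp14 (1.91). From 3 h to 12 h this list fell by a median of 2.38 in controls and changed by -0.43 in treated HSC. Of NF-κB targets, 32 of 50 rose (35 adjusted over the list alone), adjusted p = 5.04e-07 with an estimated correlation. Birc3 (2653 ± 245 against 331 ± 73.5), Nfkbia (3.9), Tnfaip3 (3.37) and Vcam1 (6.67) were among them. Of cytokines, 12 of 32 rose and 1 fell (17 and 2 adjusted over the list alone), adjusted p = 0.000648 with an estimated correlation. Of anti-apoptotic genes, 11 of 26 rose and 4 fell (11 and 4 adjusted over the list alone), adjusted p = 0.00578 with an estimated correlation, with Traf1 (4.51) up. Of antigen presentation genes, 10 of 23 rose (17 adjusted over the list alone), adjusted p = 0.027 with an estimated correlation. Examples were B2m, the light chain of MHC class I (96759 ± 8660.1 against 43684 ± 3549), and Cd74, the invariant chain of class II (2.55). Of necroptosis genes, 5 of 21 rose and 1 fell (6 and 1 adjusted over the list alone), a list call lost at adjusted p = 0.114 with an estimated correlation. Zbp1, a nucleic acid sensor (3.87), and Birc2 (1.08) rose. Mlkl, the executor of necroptosis, fell by 0.52 and was not called without any 1 of the libraries except control 1 and TNFα 3 (adjusted p from 0.0915 to 0.238). Of S phase genes, 10 of 36 fell (13 adjusted over the list alone), a list call lost at adjusted p = 0.0902 with an estimated correlation, such as Rrm1 (-0.47). Of HSC identity genes, 2 of 38 rose and 5 fell (3 and 9 adjusted over the list alone), with the list not called (adjusted p = 0.486 with an estimated correlation), with falls of Lmo2 (-1.13) and Hlf (2524 ± 284 against 8178 ± 1619). Of unfolded protein response genes, 7 of 24 rose (10 adjusted over the list alone), a list call lost at adjusted p = 0.363 with an estimated correlation. Of monocyte markers, 5 of 18 rose and 1 fell (5 and 2 adjusted over the list alone), a list call lost at adjusted p = 0.0899 with an estimated correlation, including Axl (3.1) and Csf1r (1.86).

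In the panel, Nfkb2 (2.85), Relb (4.39) and Spi1 (1.5) rose. Bcl2l1 fell by 0.99 and was not called without any 1 of the libraries except TNFα 1 (adjusted p from 0.0676 to 0.121). Cflar rose by 0.5 and was not called without any 1 of the libraries except TNFα 3 (adjusted p from 0.0558 to 0.181). limma called 1442 genes, 907 higher and 535 lower, with 3277 at an unadjusted p under 0.05. The count was 766 in the 6 libraries alone and 816 without the cultured libraries numbered 1.

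In HSC sorted 3 h after TNFα injection, NF-κB targets, cytokines and unfolded protein response genes were higher as lists. Cxcl10 rose to 11628 ± 6815 (SD, n = 3) against 57 ± 40.6 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889). Its log2 change was 7.82 (adjusted p = 7.91e-16). Cxcl9 rose to 4316 ± 2379 against 24.8 ± 19.4 and Cxcl2, which attracts neutrophils, to 1173 ± 389 against 4.87 ± 3.9. Serpina3i, of a family of protease inhibitor genes with close paralogs, was at 338 ± 58.5 against 0 ± 0 and at least 102-fold higher. A1cf rose to 362 ± 55.6 against 1.93 ± 2.69. Ly6a rose to 6766 ± 1095 against 1092 ± 203 (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), while Kit fell to 2879 ± 259 against 8593 ± 992 and Cd34 to 602 ± 54.3 against 1381 ± 106. The largest fall, of Mlph, was a ratio of 182-fold, 50.02 to 1506. Sgsh (-5.95), Lrrn4 (-5.89), Slc26a11 (-5.39) and Ppargc1a, a coactivator of mitochondrial biogenesis (-4.84), followed.

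Of NF-κB targets, 36 of 50 rose and 1 fell (40 and 2 adjusted over the list alone), adjusted p = 2.69e-05 with an estimated correlation. Birc3 (3670 ± 243 against 351 ± 65.9), Nfkbia (2944 ± 158 against 258 ± 77.9), Tnfaip3 (3.58) and Bcl3 (4.05) rose. Of cytokines, 15 of 32 rose and 2 fell (17 and 2 adjusted over the list alone), adjusted p = 0.00761 with an estimated correlation. Of anti-apoptotic genes, 11 of 26 rose and 3 fell (11 and 3 adjusted over the list alone), adjusted p = 0.0269 with an estimated correlation. Of unfolded protein response genes, 20 of 24 rose (22 adjusted over the list alone), adjusted p = 0.0207 with an estimated correlation. Manf, secreted under stress of the endoplasmic reticulum, rose to 1724 ± 273 against 400.4 ± 27.8 (ENSMUSG00000032575, chromosome 9, 106838312 to 106891979). The chaperone Hyou1 (2.41), Edem1 (1.35) and asparagine synthetase Asns (2.33) rose too. Of cholesterol synthesis genes, 14 of 25 rose and 1 fell (14 and 1 adjusted over the list alone), a list call lost at adjusted p = 0.184 with an estimated correlation, such as Hmgcs1 (1249 ± 95.8 against 265 ± 85.8) and Hmgcr (1.22). Of interferon genes, 20 of 43 rose (22 adjusted over the list alone), a list call lost at adjusted p = 0.243 with an estimated correlation, such as Gbp3 (3.46) and Gbp5 (3.98). Of antigen presentation genes, 11 of 23 rose and 2 fell (12 and 2 adjusted over the list alone), a list call lost at adjusted p = 0.301 with an estimated correlation, such as Cd74 (2.86). Of megakaryocyte genes, 4 of 20 rose and 5 fell (4 and 6 adjusted over the list alone), with the list not called (adjusted p = 0.961 with an estimated correlation), with the platelet adhesion genes Itgb3 (2.99) and Selp (4.63) up. Pfkfb3 rose to 7032 ± 612 against 369.6 ± 128.

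Of HSC identity genes, 3 of 38 rose and 16 fell (3 and 21 adjusted over the list alone), a list call lost at adjusted p = 0.0859 with an estimated correlation. Hlf fell to 3903 ± 588 against 14499.9 ± 647 and Lmo2 to 4012 ± 295 against 10346 ± 716. These cells were sorted after exposure by Sca-1, whose gene rose. In the same libraries, 2 erythroid markers rose and 2 fell (2 and 2 adjusted over the list alone). Of granule genes, 3 rose and 5 fell (4 and 5 adjusted over the list alone). Of the quiescence list, 5 of 21 rose and 4 fell (5 and 4 adjusted over the list alone), with the list not called (adjusted p = 0.984 with an estimated correlation). Rbl2 (-1.53), Txnip (-1.16) and Foxo3 (-1.09) fell, while Cdk6 (1.36) and the CDK inhibitor Cdkn1a (298 ± 110.3 against 84.1 ± 98.3) rose. Of pro-apoptotic genes, 5 of 26 rose and 1 fell (5 and 1 adjusted over the list alone), with the list not called (adjusted p = 0.706 with an estimated correlation), the median being -0.11 while the mean (0.45) and the test pointed up. Pmaip1, which encodes NOXA, rose to 164 ± 34.7 against 0.3 ± 0.52 (ratio 495-fold, 88.4 to 19606), and Apaf1 by 1.66. Of necroptosis genes, 7 of 21 rose and 1 fell (7 and 1 adjusted over the list alone), a list call lost at adjusted p = 0.151 with an estimated correlation, with Birc2 (0.94) up. Mlkl rose by 0.48 and was not called without PBS 1 or without TNFα 2 or without TNFα 3 (adjusted p from 0.0856 to 0.142).

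Relb (4.4), Nfkb2 (3.03), Traf1 (3.49), Tnf (2.37) and Spi1 (1.48) rose. Procr (-1.98), an HSC surface receptor, and Tnfrsf1b (-0.71), TNF receptor 2, fell. Bcl2l1 fell by 1.1 and was not called without PBS 2 (adjusted p = 0.0533). Flt3 fell by 1.25 and was not called without any 1 of the 6 libraries (adjusted p from 0.0577 to 0.0997). limma called 4176 genes, 2061 higher and 2115 lower, with 5909 at an unadjusted p under 0.05 and 2517 in the 6 libraries alone. Sorting followed exposure here, so changes within cells and changes in which cells passed the gates cannot be separated.

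In GMP, 3 h of culture with TNFα raised NF-κB targets and cytokines. Il1b rose to 3679.8 ± 187 (SD, n = 3) against 212 ± 57.2 (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139). Its log2 change was 4.15 (adjusted p = 0.000382). Il1a rose to 1039 ± 391 against 55.9 ± 41.8, the pentraxin gene Ptx3 to 2571 ± 443 against 229.7 ± 57.1 and the fatty acid receptor gene Gpr84 to 1605 ± 506 against 149 ± 63.7. Lta, which encodes lymphotoxin, rose by 4.02 and was not called without control 3 (adjusted p = 0.062). Nfkbia rose to 1400.1 ± 86.7 against 215 ± 52.6 and Tnfaip3 to 2671 ± 344 against 364 ± 95.2. Among the falls were Cytip (1056 ± 148 against 2130.5 ± 203) and Arhgef18 (52.8 ± 6.37 against 115 ± 9.07).

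Of NF-κB targets, 31 of 50 rose (41 adjusted over the list alone), adjusted p = 1.51e-08 with an estimated correlation, such as the adhesion molecule Icam1 (2.59) and Birc3 (1.35). Of cytokines, 9 of 32 rose (20 adjusted over the list alone), adjusted p = 3.1e-05 with an estimated correlation. Cxcl10 (28862 ± 3383 against 5624 ± 579) and Il12a (1.78) were among them. Of anti-apoptotic genes, 6 of 26 rose and 1 fell (9 and 1 adjusted over the list alone), adjusted p = 0.000648 with an estimated correlation, with Traf1 (2.99) up. Of antioxidant genes, 5 of 25 rose (7 adjusted over the list alone), a list call lost at adjusted p = 0.0592 with an estimated correlation. They included the ferritin chain Fth1 (41640.4 ± 10832 against 17053 ± 1869) and mitochondrial superoxide dismutase Sod2 (1.06). Of interferon genes, 4 of 43 rose (6 adjusted over the list alone), a list call lost at adjusted p = 0.486 with an estimated correlation, such as Gbp2 (1.57). Igsf6 (1.6), a myeloid surface protein, and Car2, a carbonic anhydrase (5676 ± 748 against 743 ± 128), also rose.

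limma called 196 genes, 156 higher and 40 lower, with 1465 at an unadjusted p under 0.05. In other fits, given below, the count ran from 48 in the 6 libraries alone to 363 with DESeq2. GMP TNFα 3 stood apart from TNFα 1 and TNFα 2 (residual SD of 0.71 against 0.54 and 0.56), and without it limma called 155 genes. Lhfpl2 (-1.19) was not called without any 1 of the 6 libraries (adjusted p from 0.0691 to 0.158). Rgs2 (-1.15) was not called without control 3 or without TNFα 1 (adjusted p from 0.064 to 0.0793). Il17ra (-1.03) was not called without control 2 or without TNFα 3 (adjusted p from 0.0983 to 0.188). Relb (1.94) was not called without any 1 of the libraries except TNFα 3 (adjusted p from 0.0852 to 0.249). Nfkb2 (1.36) was not called without any 1 of the libraries except TNFα 3 (adjusted p from 0.0521 to 0.155). Tnf (2.13) was not called without any 1 of the libraries except TNFα 1 (adjusted p from 0.052 to 0.169).

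In GMP cultured with TNFα for 12 h, interferon genes were the list with the most members raised. Irg1, the enzyme that makes itaconate, rose to 934 ± 134 (SD, n = 3) against 17 ± 15.8 (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573). Its log2 change was 6.14 (adjusted p = 1.74e-10). Il1a rose to 213 ± 22.5 against 0.733 ± 1.27 (ratio 255-fold, 86.8 to 1238), Emr4 by 5.89, the matrix protease gene Mmp14 by 5.33 and Rtp4 to 249 ± 177 against 6.33 ± 5.62. Falls included Serpinb1a, an inhibitor of neutrophil proteases (678 ± 142 against 1704 ± 273), and Pdcd4 (384 ± 21.9 against 927 ± 14.9). Lyz2, the myeloid lysozyme, rose to 12393 ± 1715 against 3181 ± 789. Mpo fell by 1.08 and was not called without any 1 of the libraries except TNFα 3 (adjusted p from 0.0786 to 0.29).

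Of interferon genes, 33 of 43 rose (39 adjusted over the list alone), adjusted p = 5.95e-05 with an estimated correlation, such as Ifi44 (218 ± 120.1 against 10.2 ± 5.75), Gbp2 (2.79) and Parp14 (1.73). Of NF-κB targets, 26 of 50 rose (33 adjusted over the list alone), adjusted p = 1.51e-08 with an estimated correlation, with Nfkbia (765 ± 105 against 108 ± 20.8) and Tnip3 (3.81). Of cytokines, 13 of 32 rose (17 up and 1 down adjusted over the list alone), adjusted p = 7.28e-06 with an estimated correlation, with Cxcl10 (2795 ± 1233 against 157 ± 52.6), Il1b (4.67) and Ccl4 (3.31). Of anti-apoptotic genes, 6 of 26 rose and 1 fell (7 and 1 adjusted over the list alone), adjusted p = 0.00391 with an estimated correlation, with Traf1 (4.02) up. Of antigen presentation genes, 6 of 23 rose (9 adjusted over the list alone), adjusted p = 0.0243 with an estimated correlation, with Cd74 (2.02). Of dendritic cell markers, 2 of 10 rose (3 adjusted over the list alone), adjusted p = 0.0141 with an estimated correlation, Cd74 being 1 of them. Of antioxidant genes, 4 of 25 rose (8 up and 1 down adjusted over the list alone), adjusted p = 0.0463 with an estimated correlation, with Sod2 (1.46). Cholesterol synthesis genes were lower as a list (adjusted p = 0.0439 with an estimated correlation), with 7 lower adjusted over the list alone. Over all genes 1 was called, Stard4 (-0.68), and not without any 1 of the 6 libraries (adjusted p from 0.0583 to 0.109). Of immediate early genes, 3 of 33 rose (7 adjusted over the list alone), a list call lost at adjusted p = 0.462 with an estimated correlation, such as Dusp1 (1.87).

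In the panel, Birc3 (1.47), Tnfaip3 (2.81), Relb (2.92) and Nfkb2 (2.03) rose. Tnf rose by 1.88 and was not called without any 1 of the 6 libraries (adjusted p from 0.105 to 0.183). Procr rose by 2.15 and was not called without any 1 of the 6 libraries (adjusted p from 0.0642 to 0.188). limma called 377 genes, 323 higher and 54 lower, with 1313 at an unadjusted p under 0.05. The count was 234 without control 1, 240 without TNFα 1 and 150 without the cultured libraries numbered 1. Mmp8 (-3.41) was not called without control 1 (adjusted p = 0.0723). Cxcr2 (-2.02) was not called without control 1 or without TNFα 2 (adjusted p from 0.0837 to 0.0974). Prss57 (-1.98) was not called without any 1 of the 6 libraries (adjusted p from 0.0627 to 0.232).

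In GMP sorted 3 h after TNFα injection, NF-κB targets, cytokines and anti-apoptotic genes were higher as lists. Saa3, an acute-phase serum amyloid, rose to 7017 ± 1040.1 (SD, n = 3) against 9.7 ± 7.95 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700). Its log2 change was 9.6 (adjusted p = 1.38e-13). Ptx3 rose to 921 ± 72.5 against 2.53 ± 2.25 and Irg1 to 1061 ± 92.1 against 5.1 ± 4.78. Cd38, an enzyme that degrades NAD, rose by a ratio of 983-fold, 176 to 38847, and Fpr2, a formyl peptide receptor, by 933-fold, 167 to 36876. The cholesterol exporter gene Abcg1 fell to 9.17 ± 1.97 against 148 ± 22.5 and Lbh to 49.97 ± 3.64 against 462 ± 18. Rnf144b (-3.84), Ypel2 (-3.07) and Cxcr2, the neutrophil chemokine receptor (26.1 ± 8.81 against 219.7 ± 47.5), fell too. Lyz2 rose to 21248 ± 5804 against 3457 ± 1138 and haptoglobin, Hp, by 2.23.

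Of NF-κB targets, 38 of 50 rose and 2 fell (39 and 2 adjusted over the list alone), adjusted p = 5.87e-07 with an estimated correlation. Sod2 (10668 ± 2049.5 against 1041 ± 104) and the pattern receptor genes Tlr2 (3.32) and Clec4e (4.77) rose. Of cytokines, 15 of 32 rose and 2 fell (17 and 2 adjusted over the list alone), adjusted p = 0.00325 with an estimated correlation, with Cxcl10 (4.77) up. Of anti-apoptotic genes, 10 of 26 rose and 1 fell (13 and 1 adjusted over the list alone), adjusted p = 0.00717 with an estimated correlation, with Birc3 (2.07) up and Bcl2 (-1.33) down. Of antioxidant genes, 8 of 25 rose and 1 fell (8 and 1 adjusted over the list alone), a list call lost at adjusted p = 0.121 with an estimated correlation, with the cystine transporter Slc7a11 (342 ± 22.1 against 38.1 ± 15.9) and Fth1 (2.15) up. Of immediate early genes, 11 of 33 rose (12 adjusted over the list alone), a list call lost at adjusted p = 0.392 with an estimated correlation, such as Maff (4.01). Of interferon genes, 7 of 43 rose and 6 fell (7 and 6 adjusted over the list alone), with the list not called (adjusted p = 0.984 with an estimated correlation), with Gbp5 (4.08) up. Of megakaryocyte genes, 3 of 20 rose and 3 fell (5 and 3 adjusted over the list alone), with the list not called (adjusted p = 0.777 with an estimated correlation). Thbs1, thrombospondin (6.22), and Plek (3.46) were up and Itgb3 (-1.76) down. The death receptor gene Fas (128 ± 24.3 against 6.9 ± 5.2), Pmaip1 (3.04) and Cdkn1a (2.2) rose, and Casp2 (-1.33) fell.

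Tnfrsf1b rose to 2637 ± 59.6 (SD, n = 3) against 900 ± 70.7 in GMP, and Mlkl fell by 0.82. Relb (5.86), Nfkb2 (3.58), Traf1 (4.86), Tnfaip3 (2.13), Nfkbia (2.55), Tnf (2.43) and Mcl1 (0.79) rose. Ripk1 fell by 0.68 and was not called without PBS 1 or without PBS 2 or without TNFα 2 (adjusted p from 0.0604 to 0.12). Mpo fell by 0.92 and was not called without any 1 of the libraries except TNFα 1 (adjusted p from 0.0664 to 0.113). Spi1 rose by 0.77 and was not called without any 1 of the libraries except PBS 2 and TNFα 3 (adjusted p from 0.0617 to 0.125). Of the sort genes, Ly6a rose by 1.13 and was not called without PBS 1 or without TNFα 3 (adjusted p from 0.0826 to 0.146). Cd34 fell by 0.67 and was not called without any 1 of the libraries except TNFα 1 and TNFα 3 (adjusted p from 0.0511 to 0.157). Slamf1 rose by 2.01, from 1 read to 13 over the 3 libraries. limma called 2082 genes, 1152 higher and 930 lower, with 4120 at an unadjusted p under 0.05. Ripk3, Casp8, Tnfrsf1a, Cdkn1c, Cebpa, Mki67 and Mecom of the panel were not called by limma in any of the 6 TNFα comparisons.

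**Figure D2:**
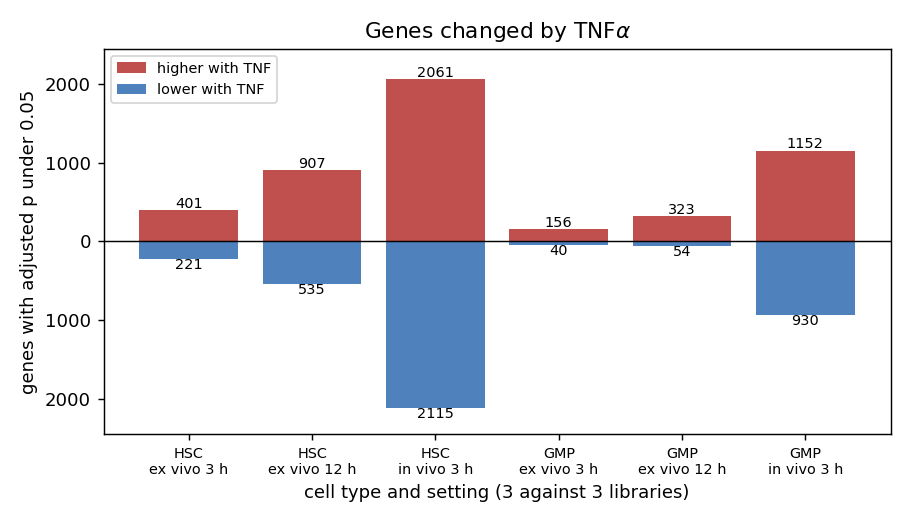
Genes called with an adjusted p under 0.05 by limma in each cell type and setting, 3 against 3 libraries. Genes higher with TNFα stand above the axis and genes lower below it. Counts run from 156 higher and 40 lower in GMP after 3 h of culture to 2061 higher and 2115 lower in HSC of injected mice.

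**Figure D3:**
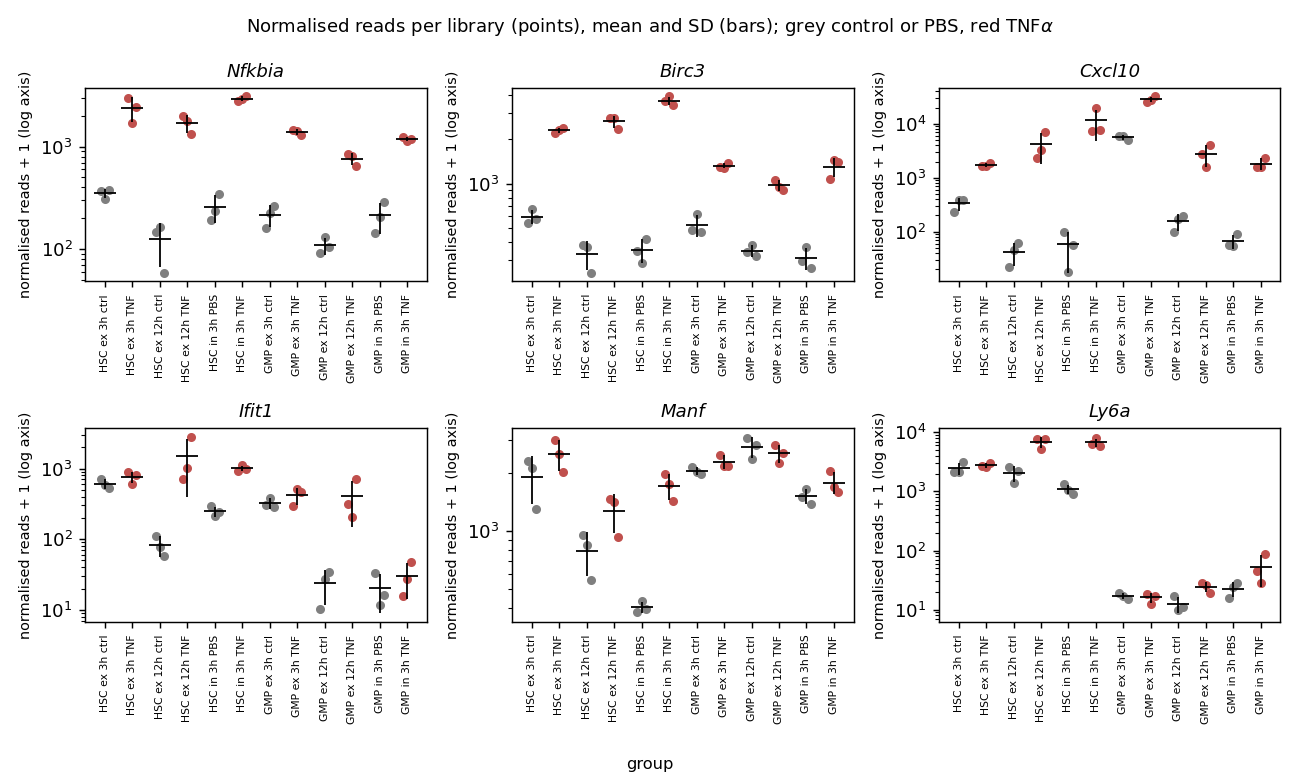
Normalised reads plus 1 on a log axis for 6 genes in all 12 groups. Points are libraries (grey control or PBS, red TNFα) and bars the mean and SD of 3. Nfkbia and Birc3 were called higher with TNFα in all 6 settings.

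**Figure D4:**
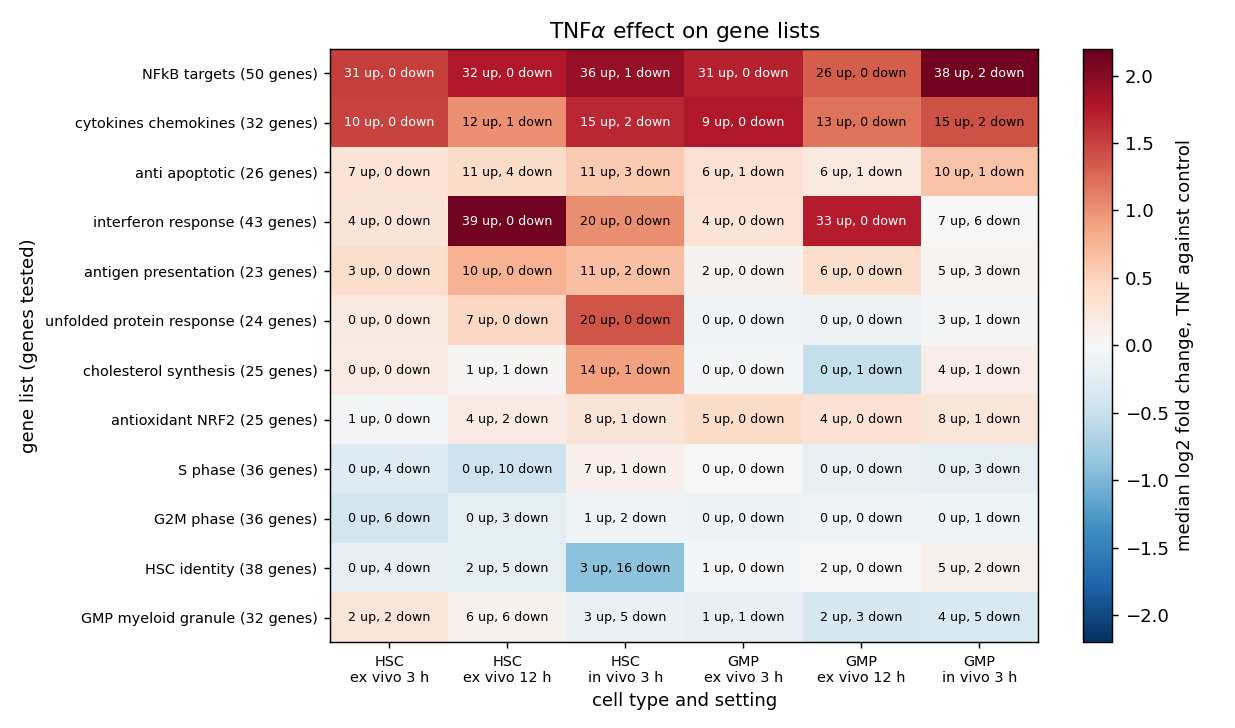
Median log2 change with TNFα of 12 gene lists (vertical, with the number of genes tested) in the 6 settings (horizontal). Color gives the median and the text the members called higher and lower by limma. Of 43 interferon genes, 39 were called higher in HSC and 33 in GMP at 12 h of culture, and 4 in each at 3 h.

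The remaining lists were called with an estimated correlation in none of the 6 TNFα comparisons, over which their adjusted p had these ranges. They were 0.767 to 0.934 for TNF receptor signalling, 0.701 to 0.987 for pro-apoptotic genes, 0.217 to 0.987 for p53 targets and 0.301 to 0.987 for quiescence. They were 0.452 to 0.884 for myeloid regulators, 0.536 to 0.987 for granule genes and 0.205 to 0.991 for glycolysis. Markers of other cells gave 0.767 to 0.987 for neutrophils, 0.0899 to 0.987 for monocytes, 0.221 to 0.991 for erythroid cells and 0.42 to 0.987 for basophils and mast cells. They gave 0.325 to 0.884 for B cells, 0.768 to 0.987 for T and NK cells and 0.551 to 0.987 for stroma. The range was 0.767 to 0.991 for oxidative phosphorylation and 0.64 to 0.991 for ribosomal proteins. It was 0.987 to 0.991 for mitochondrially encoded and 0.916 to 0.991 for sex-linked genes. Single members were called, such as Irf1, an interferon-induced transcription factor, in HSC (1.42 at 3 h, 1.65 at 12 h, 2.53 in vivo). Csf2rb, a receptor chain for IL-3 and GM-CSF, rose in vivo in HSC (1.44) and GMP (1.91).

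Genes called in the same direction in both cell types were counted against the number expected if calls were independent. At 3 h of culture, 83 genes were higher in both (3.62 expected) and 7 lower (0.511 expected). At 12 h, 198 were higher (16.9 expected) and 19 lower (1.67 expected). In vivo, 601 were higher (137 expected) and 401 lower (114 expected). Within HSC, 217 genes were higher at both culture times (21.02 expected) and 176 both in culture at 3 h and in vivo (47.8 expected). Within GMP these numbers were 108 (2.91 expected) and 101 (10.4 expected). The groups compared at 3 h and 12 h or in culture and in vivo share no control.

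The interaction of cell type and TNFα tested whether responses differed, with the log2 change in HSC first. In vivo, 1369 genes differed, 685 higher and 684 lower in HSC, by response or by which cells passed the gates. Papss2, which makes a sulfate donor, changed by 5.75 against -0.24, Cd83 by 6.46 against 0.71, and Inhba, an activin subunit, by -1.94 against 7.41. Saa3 changed by -0.64 against 9.6 and Cd38 by -0.52 against 7.91. Of unfolded protein response genes, 18 of 24 were higher (21 adjusted over the list alone), adjusted p = 0.0153 with an estimated correlation. Of HSC identity genes, 3 of 38 were higher and 10 lower (3 and 17 adjusted over the list alone), adjusted p = 0.0289 with an estimated correlation, many of them at low levels in GMP. Of NF-κB targets, 8 of 50 were higher and 8 lower (11 and 14 adjusted over the list alone), with the list not called (adjusted p = 0.961 with an estimated correlation). Of interferon genes, 11 of 43 were higher (13 adjusted over the list alone), a list call lost at adjusted p = 0.301 with an estimated correlation. Of necroptosis genes, 4 of 21 were higher (7 adjusted over the list alone), a list call lost at adjusted p = 0.0506 with an estimated correlation. In the panel, Birc3 differed by 1.32, Birc2 by 1.28, Mlkl by 1.3, Tnfrsf1b by -2.26 and Bcl2l1 by -1.94.

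At 12 h of culture, 294 responses differed between HSC and GMP. Cxcl9 changed by 8.46 against 1.54, Loxl2, a lysyl oxidase, by 6.07 against 0.19 and Mmp14 by 0.4 against 5.33. Birc3 differed by 1.55. Tcrg-C1 was at 0 in TNFα-treated HSC against 84 ± 47.9 in their controls, at least 32.4-fold lower. Of NF-κB targets, 5 of 50 were higher and 2 lower (15 and 4 adjusted over the list alone), a list call lost at adjusted p = 0.127 with an estimated correlation. At 3 h, 47 responses differed, among them Pfkfb3 (1.63 against -0.08), Il12a (-0.68 against 1.78) and Tma16 (-0.04 against 2.03). That count was 17 to 57 in fits without 1 library. It was 2 in the 12 libraries alone, 14 without the libraries numbered 1, 91 with replicate as a block and 100 with DESeq2.

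Between 12 h and 3 h of culture, 377 responses differed in HSC and 10 in GMP, with the change at 12 h given first. In HSC, Cxcl9 changed by 8.46 against 2.2, Lpl, a lipase, by 5.58 against -0.58 and Deptor by -4.13 against -0.24. In GMP, Rtp4 changed by 5.12 against 0.29, Irg1 by 6.14 against 1.69 and Ifit1 by 4.07 against 0.35. Of interferon genes in HSC, 19 of 43 were higher (36 adjusted over the list alone), adjusted p = 0.00717 with an estimated correlation. Of interferon genes in GMP, 6 of 43 were higher (30 adjusted over the list alone), adjusted p = 0.00121 with an estimated correlation. Birc3 in HSC differed by 1.06, and its level in controls was lower at 12 h than at 3 h. In GMP all 10 calls were higher and 0 lower by limma, with 587 genes at an unadjusted p under 0.05. For GMP, edgeR with TMM called 12 genes, DESeq2 36, a fit with replicate as a block 25 and the 12 libraries alone 1. In HSC the 12 libraries alone gave 104 and a fit without those numbered 1 122.

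Between routes at 3 h, 2097 responses differed in HSC and 643 in GMP, the change in vivo first. Dose, order of sorting, sex-linked expression and culture differed with the route. In HSC, Spp1, an adhesion protein, changed by 5.6 against -0.85, Pmaip1 by 7.04 against 0.38 and Srgap3 by -4.8 against 0.6. In GMP, Saa3 changed by 9.6 against 2.26, Thbs1 by 6.22 against -0.72 and Abcg1 by -3.88 against -0.55. Of unfolded protein response genes in HSC, 15 of 24 were higher (19 adjusted over the list alone), a list call lost at adjusted p = 0.0558 with an estimated correlation. Of cholesterol genes in HSC, 9 of 25 were higher (12 adjusted over the list alone), a list call lost at adjusted p = 0.3 with an estimated correlation. Of NF-κB targets in GMP, 12 of 50 were higher and 3 lower (16 and 5 adjusted over the list alone), a list call lost at adjusted p = 0.074 with an estimated correlation. Birc3 in HSC differed by 1.44, and Relb by 3.92 and Nfkb2 by 2.22 in GMP. In other fits, given below, counts fell to 912 in HSC and ran from 258 to 1077 in GMP.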

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

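The tests of sequencing depth, replicate spread, GMP in the sorted cells, other progenitors and splits with the shared effect removed were chosen after their results had been seen, while those of falling controls, single libraries, scaling and the first count of sample splits were written first. Every result in this part was taken up because the response to TNFα differed between HSC and GMP, or between times or routes within a cell type, by limma's test of the difference. Values are differences of log2 changes, the first-named group minus the second, with the adjusted p in parentheses; for genes near 0 reads in a group they are fitted values and no bounds.

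Between HSC and GMP in culture at 3 h, 47 genes differed. They included Mgst2 3.45 (0.0443), Irs2 2.39 (0.0135), Rnf125 2.12 (0.0288), Ctdspl 2.07 (0.0129) and Pfkfb3 1.71 (0.000426), an activator of glycolysis. On the GMP side were Il12a -2.46 (0.000426), Rasgef1b -2.46 (0.0315), Tma16 -2.06 (2.6e-07), Csf1 -1.95 (0.0329) and Pot1b -1.88 (0.0469). Mgst2 was not called without any 1 of the libraries except HSC control 1 and HSC control 3 (adjusted p from 0.0632 to 0.112). Rnf125 was not called without any 1 of the libraries except HSC control 1, HSC TNFα 2, GMP control 2 and GMP TNFα 3 (adjusted p from 0.0507 to 0.112). Ctdspl was not called without GMP control 3 (adjusted p = 0.0502). Rasgef1b was not called without any 1 of the libraries except HSC control 1, HSC control 3, HSC TNFα 2 and GMP TNFα 2 (adjusted p from 0.0505 to 0.0915). Csf1 was not called without any 1 of the libraries except HSC control 3, HSC TNFα 2, GMP control 2 and GMP TNFα 3 (adjusted p from 0.0514 to 0.113). Pot1b was not called without any 1 of the libraries except HSC control 1, HSC TNFα 2, GMP TNFα 1 and GMP TNFα 2 (adjusted p from 0.0792 to 0.157). With the libraries of the comparison alone, 1 of these 10 calls remained.

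At 12 h, 294 genes differed. The cell death inhibitors Birc2 1.08 (0.0212) and Birc3 1.55 (6.47e-05) responded more in HSC, Birc2 not being called without HSC control 2 or without HSC TNFα 1 or without HSC TNFα 2 or without GMP control 1 or without GMP control 3 or without GMP TNFα 2 (adjusted p from 0.0613 to 0.108). So did Cxcl9 6.92 (4.09e-07), Fcer2a 6.33 (0.000529), Nrg1 6.04 (2.67e-09), S1pr3 5.9 (0.000144) and Loxl2 5.88 (0.00152). Lower in HSC than in GMP were Tcrg-C1 -5.68 (0.000124), Ptx3 -5.66 (0.000429), Mmp14 -4.93 (0.000279), Leprel1 -4.03 (0.00422) and Cd36 -3.79 (0.021), the last not called without HSC control 1 or without HSC control 2 or without HSC TNFα 1 or without GMP control 3 or without GMP TNFα 1 (adjusted p from 0.0559 to 0.0929).

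In vivo, 1369 genes differed, by response or gating. In the panel these were Birc2 1.28 (0.00127), Birc3 1.32 (0.000185), Bcl2l1 -1.94 (0.00244), Mlkl 1.3 (0.00022), Tnfrsf1b -2.26 (4.08e-07), which rose in GMP and fell in HSC, and Ripk1 0.91 (0.0399), not called without any 1 of the libraries except HSC PBS 2, HSC TNFα 1, GMP PBS 3 and GMP TNFα 1 (adjusted p from 0.0506 to 0.15). Beyond the panel, Serpina3i 7.73 (3.52e-07), Tnfrsf9 7.25 (3.12e-08), A1cf 7.04 (0.00027), Papss2 5.98 (7.07e-14) and Cd83 5.75 (0.00371) responded more in HSC, and Saa3 -10.24 (5.45e-10), Inhba -9.35 (1.41e-10), Cd38 -8.43 (5.07e-09), Fpr2 -7.91 (1e-07) and Ptx3 -7.91 (4.88e-07) in GMP.

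In HSC, 377 responses differed between 12 h and 3 h of culture. These included Birc3 1.06 (0.00784), Cd52 7.12 (1.99e-06), the chemokines Ccl22 6.37 (0.00451) and Cxcl9 6.26 (3.09e-06), Lpl 6.16 (1.95e-09) and Gas7 5.51 (2.17e-06), and in the other direction Nav2 -4.33 (1.99e-06), Cables1 -4.07 (0.00704), Deptor -3.89 (4.03e-06), Dlg2 -3.85 (0.00932) and Aqp1 -3.73 (0.03). Such differences do not separate a larger rise with TNFα from a fall in controls. Birc3 was lower in controls at 12 h than at 3 h. In untreated HSC, 29 of 50 NF-κB targets were lower at 12 h and 4 higher, and 16 of 32 cytokines were lower and 1 higher. Aqp1 was not called without any 1 of the libraries except 3 h control 3, 3 h TNFα 1, 12 h control 2 and 12 h TNFα 2 (adjusted p from 0.0551 to 0.118), and Traf1 2.18 (0.0247) not without 3 h control 3 or without 3 h TNFα 2 or without 12 h control 3 or without 12 h TNFα 1 or without 12 h TNFα 2 (adjusted p from 0.056 to 0.116). In GMP, 10 responses differed, with Rtp4 4.83 (0.00146), Irg1 4.45 (0.00284), Usp18 3.89 (0.00841), Ifit1 3.73 (0.00414) and Ifi44 3.51 (0.00773) the largest. Of these, Usp18 was not called without 3 h control 2 or without 3 h TNFα 3 or without 12 h control 1 or without 12 h TNFα 3 (adjusted p from 0.056 to 0.0819) and Ifi44 not without 3 h TNFα 1 or without 12 h control 1 or without 12 h TNFα 3 (adjusted p from 0.0564 to 0.0687). With the libraries of the GMP comparison alone, 0 of these 5 calls remained.

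Between routes at 3 h, 2097 responses differed in HSC. Birc3 1.44 (4.85e-05) and Cdkn1a 1.77 (0.046) responded more in vivo. Cdkn1a was not called without any 1 of the libraries except 3 h control 2, in vivo PBS 3 and in vivo TNFα 1 (adjusted p from 0.0553 to 0.212). Higher in vivo too were Pmaip1 6.65 (3.5e-09), Spp1 6.45 (9.3e-09), Steap4 6.24 (1.31e-06), Serpina3i 6.19 (1.64e-05) and Il13ra1 6.12 (2.34e-09). In the other direction, Pdgfb -6.52 (9.22e-06), Lrrn4 -5.7 (0.000697), Srgap3 -5.4 (4.35e-09), Kcnip3 -5.23 (8.97e-06) and Fam69b -4.84 (0.000316) were lower in vivo. In GMP, 643 responses differed. Relb 3.92 (0.000794), Nfkb2 2.22 (0.00337), Saa3 7.33 (2.05e-06), Thbs1 6.94 (1.26e-06), Cd38 6.56 (2.05e-06), Irg1 6.1 (9.6e-07) and Rnd3 5.82 (2.37e-06) rose more in vivo, and Abcg1 -3.33 (3.51e-07), Rnf24 -3.1 (7.76e-09) and Lbh -3.05 (2.57e-05) had a lower log2 change in vivo. Traf1 1.87 (0.0473) was not called without any 1 of the libraries except 3 h control 3, 3 h TNFα 2, in vivo PBS 2 and in vivo TNFα 3 (adjusted p from 0.05 to 0.183). Mlkl -0.87 (0.024) was not called without 3 h control 1 or without 3 h control 3 or without 3 h TNFα 3 or without in vivo PBS 1 or without in vivo TNFα 2 (adjusted p from 0.0561 to 0.0726). Il1a -4.28 (0.0318) was not called without any 1 of the libraries except 3 h control 3, 3 h TNFα 2, in vivo PBS 1, in vivo PBS 3 and in vivo TNFα 1 (adjusted p from 0.0503 to 0.117). Ednrb -4.13 (0.0174) was not called without 3 h control 3 or without in vivo PBS 1 or without in vivo PBS 2 or without in vivo TNFα 2 or without in vivo TNFα 3 (adjusted p from 0.0527 to 0.0654).

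The late interferon response in culture is the first pattern weighed. In HSC the list fell by a median of 2.38 from 3 h to 12 h in controls (spread 0.26) and its median change in TNFα-treated libraries was -0.43 (spread 0.15), so falling controls may account for the late difference there. In GMP the treated libraries rose by a median of 0.72 (spread 0.22) while controls fell by 0.80 (spread 0.28). The spread, a standard error of the median, takes members as independent, but their estimated correlation was 0.317. Of the 43 members, 13 rose and 5 fell past the threshold in treated GMP. This argues against falling controls as the whole cause for those 13. The test written first did so for the list. Tested among all genes, camera gave p = 0.249 with an estimated correlation, so for the list it stays open. A single library carried neither difference, since the lowest median over the 12 fits that left out 1 library was 1.34 in HSC and 1.32 in GMP. A response to interferon made in culture would be biological and was not tested.

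The second pattern was the larger number of genes called in vivo than in culture at 3 h. In vivo libraries held 0.965 times the reads of cultured ones in HSC (11.2 against 11.6 M) and 1.01 times in GMP (13.3 against 13.1 M), so depth does not account for counts several times higher. Their residual SD was 0.958 and 0.974 times that in culture. The model pools the spread of all groups into a common error for each gene, so these ratios do not bear on the counts. The depth bound was first set at 1 and then at 1.1, after the GMP value was seen. Route, dose, sex-linked expression and culture itself, whose controls differed from PBS controls in 6974 genes in HSC, differ together and cannot be told apart. Signals from other marrow cells in the animal remain a possible biological explanation that was not tested.

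The third pattern was the fall of HSC identity genes in HSC of injected mice, with 3 of 38 members higher and 16 lower. The list call was lost with an estimated correlation (camera adjusted p = 0.0859). The median change of the list was -0.91 under the deposited scaling and -0.91 under TMM scaling. The choice between these scalings thus did not matter, but an error common to both was not tested. GMP in the sorted cells would have had to make up 46.7 percent, and Mpo reached 0.138 percent of the GMP level, Elane 0.168, Igsf6 0.345 and Lyz2 7.64, while Srgn, abundant in HSC of PBS mice too, reached 73.1 percent. That test first used the gene with the highest share, Srgn, and was changed to the lowest because the HSC baseline of Srgn would hide any share. Other progenitors that entered the gate as Sca-1 rose stay open: the erythroid list changed by a median of -0.26 (spread 0.55), and an earlier test on Flt3 was dropped because Flt3 also fell in HSC sorted before exposure. A fall within stem cells stays open as well. In HSC cultured for 12 h, which were sorted before exposure, Hlf and Lmo2 fell, but the list had a median of -0.22 with 2 of 38 members higher and 5 lower (3 and 9 adjusted over the list alone) and was not called (adjusted p = 0.486 with an estimated correlation).

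Other splits of the samples were counted for each number of genes. For the 6 effects of TNFα and for HSC against GMP, 3 against 3 libraries give too few splits for a share under 0.05; the real count and the highest of the others were 622 and 137, 1442 and 14, 4176 and 52 in HSC (3 h, 12 h, in vivo), 196 and 1, 377 and 7, 2082 and 5 in GMP, and 7153 and 4 for HSC against GMP, the real split being 1 of 10 in each. For differences of effects, splits that exchange labels in 1 arm leave the effect of the other arm whole, so high counts were built in and those splits cannot decide. Out of 100 splits, those with as many genes numbered 5 for HSC against GMP at 3 h (47 against 216 at most in the others), 9 at 12 h (294 against 370) and 1 in vivo (1369 against 1114). They numbered 10 for HSC by time (377 against 689), 6 for HSC by route (2097 against 2397), 10 for GMP by time (10 against 62) and 8 for GMP by route (643 against 946). Among the 81 splits that exchange labels in both arms, added later, the highest counts were 216, 3 and 4 for HSC against GMP (3 h, 12 h, in vivo), 155 and 56 for HSC by time and route and 1 and 3 for GMP.

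A further count of 100 splits, also added later, was made with the shared effect removed, the part of the response common to both arms. On that count only the real split called as many genes for HSC against GMP at 12 h (294 against 51) and in vivo (1369 against 253). The same held for HSC by route (2097 against 645) and GMP by route (643 against 48). A share of 1 in 100 is the lowest this count can give, and each split exchanged at most 1 library per arm. The count therefore cannot exclude chance. For the other 3 the share was under 0.05 too, but another split called more genes than the real one, so their counts stay uncertain. For HSC by time, 2 of 100 splits called as many (377 against 535). The split with 535 genes exchanged libraries numbered 1 and 3 at both times, and with replicate as a block that comparison had 534 genes. For GMP by time it was 2 of 100 (10 against 12), and limma called 1 gene in the 12 libraries alone and 1 without the cultured libraries numbered 1. For HSC against GMP at 3 h it was 4 of 100, and the other 3 called 601, 268 and 188 genes against 47. These splits exchanged HSC TNFα 1 with HSC control 2 and GMP TNFα 3 with any GMP control, and the reason for their high counts was not tested. With replicate as a block, 91 genes differed there. The splits took no account of the replicate numbers.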

How the results depend on the processing

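The fits with edgeR and TMM, TMM-scaled values, 1 cell type alone and without cultured libraries numbered 1 were chosen after the data were seen. No count of genes reversed direction, and no named gene did in any alternative run. Counts that moved by more than 1.5 times follow, and the cause was not tested. With the libraries of a comparison alone, limma called 43, 766 and 2517 genes for HSC at 3 h, 12 h and in vivo, 48 for GMP at 3 h, 2 for HSC against GMP at 3 h, 104 for HSC by time, 912 for HSC by route and 1 for GMP by time. With 1 cell type alone it called 274 for HSC at 3 h, 350 for GMP at 3 h, 190 for HSC by time, 1306 for HSC by route, 3 for GMP by time and 1077 for GMP by route. Replicate as a block gave 352 for GMP at 3 h, 91 for HSC against GMP at 3 h, 25 for GMP by time and 1047 for GMP by route, and DESeq2 gave 363, 100, 36 and 971 for the same. A pseudocount of 5 gave 72 and 18, and no filter 72 and 16, for HSC against GMP at 3 h and GMP by time. Without cultured libraries numbered 1, counts were 300 and 816 for HSC at 3 h and 12 h, 99 and 150 for GMP, 14 and 119 for HSC against GMP, 122 for HSC by time, 1 for GMP by time and 258 for GMP by route. Of 462 list tests, 139 were called with the preset and 36 with an estimated correlation.

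Leaving out 1 library at a time gave 400 to 637, 1062 to 1257 and 3419 to 3592 genes for HSC (3 h, 12 h, in vivo) and 125 to 183, 234 to 280 and 1440 to 1713 for GMP. It gave 17 to 57, 200 to 259 and 1079 to 1231 for HSC against GMP, 277 to 352 and 1768 to 2079 for HSC by time and route, 8 to 14 and 441 to 685 for GMP, and 6258 to 6768 for the controls. The libraries that moved a count by over 1.5 times were HSC TNFα 3 (400), GMP control 1 (128) and control 3 (125) at 3 h, GMP control 1 (234) and TNFα 1 (240) at 12 h, and for HSC against GMP at 3 h GMP control 3 (17), GMP control 1 (18), HSC TNFα 3 (30) and GMP TNFα 1 (30). edgeR with TMM called 485, 1420 and 3781 genes in HSC and 235, 379 and 1965 in GMP. Named genes kept their call in every such fit for 41 of 72, 72 of 98 and 90 of 117 calls in HSC, 24 of 46, 32 of 50 and 78 of 105 in GMP and 143 of 147 between the controls. With the libraries of a comparison alone, 8, 56 and 85 calls in HSC and 12, 35 and 91 in GMP remained. For differences of responses between HSC and GMP, 1 of 10, 11 of 12 and 14 of 16 calls remained (3 h, 12 h, in vivo). By time and route, 5 of 12 and 11 of 12 remained in HSC, and 0 of 5 and 12 of 14 in GMP. TMM scaling moved the median of all genes between HSC and GMP from 0.116 to 0.051. Replicates of 1 number resembled each other weakly (correlations of 0.003 to 0.203) but best among the 3 numbers in 17 of 18 cases. With the sex-linked genes of the cultured libraries numbered 1, this is evidence of a shared origin, which the main model leaves out. The block fit used each number as a block over both cell types and all settings, so it allows for such an origin only in part. Depth limits genes near 0 reads, where 1 read was worth up to 1.71 units.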

Other observations

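The tests in this part were chosen after the data were seen, and its comparisons of controls were run for description. Culture alone changed both cell types. Untreated HSC were compared at 12 h against 3 h of culture. Of S phase genes, 29 of 36 were higher (32 adjusted over the list alone), adjusted p = 0.00751 with an estimated correlation. Of G2/M genes, 29 of 36 were higher (30 adjusted over the list alone), adjusted p = 0.0402 with an estimated correlation. Mcm2, a helicase of DNA replication, was at 1936 ± 87.1 (SD, n = 3) against 347 ± 63.1. Of interferon genes, 36 of 43 were lower (36 adjusted over the list alone), adjusted p = 0.037 with an estimated correlation. Of NF-κB targets, 4 of 50 were higher and 29 lower (4 and 32 adjusted over the list alone), adjusted p = 0.0134 with an estimated correlation. Of cytokines, 1 of 32 were higher and 16 lower (1 and 16 adjusted over the list alone), adjusted p = 0.0134 with an estimated correlation. Of cholesterol synthesis genes, 20 of 25 were lower (21 adjusted over the list alone), adjusted p = 0.0155 with an estimated correlation, such as Hmgcs1 (1014 ± 199 against 7001 ± 1250.5). Slc7a11 was at 91.4 ± 22.4 against 4396 ± 1702. Untreated GMP were compared in the same way. Of their NF-κB targets, 15 of 50 were lower (19 adjusted over the list alone), adjusted p = 0.0116 with an estimated correlation. Of cytokines, 7 of 32 were lower (9 adjusted over the list alone), adjusted p = 0.0134 with an estimated correlation, with Cxcl10 at 157 ± 52.6 against 5624 ± 579. Of glycolysis genes, 7 of 24 were higher (12 adjusted over the list alone), adjusted p = 0.0218 with an estimated correlation. limma called 5066 genes between the times in HSC and 1605 in GMP.

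Cells cultured for 3 h without TNFα were also compared with cells of PBS-injected mice. Route and the sex of the mice, by sex-linked genes, differ with culture here. Of cholesterol synthesis genes in cultured HSC, 20 of 25 were higher (20 adjusted over the list alone), adjusted p = 0.0134 with an estimated correlation, with Hmgcr at 8302 ± 979.7 against 828 ± 156. Of cytokines, 18 of 32 were higher and 3 lower (18 and 3 adjusted over the list alone), adjusted p = 0.0134 with an estimated correlation. Of HSC identity genes, 2 of 38 were higher and 24 lower (3 and 24 adjusted over the list alone), adjusted p = 0.0134 with an estimated correlation. Cdkn1a was at 3539 ± 698 against 84.1 ± 98.3. Of NF-κB targets in cultured GMP, 27 of 50 were higher and 5 lower (32 and 5 adjusted over the list alone), adjusted p = 0.00751 with an estimated correlation. Of anti-apoptotic genes, 13 of 26 were higher and 2 lower (13 and 2 adjusted over the list alone), adjusted p = 0.0134 with an estimated correlation. Of cytokines, 15 of 32 were higher and 2 lower (15 and 2 adjusted over the list alone), adjusted p = 0.0129 with an estimated correlation, with Cxcl10 at 5624 ± 579 against 66.9 ± 20.4. Of antioxidant genes, 12 of 25 were higher and 2 lower (14 and 2 adjusted over the list alone), adjusted p = 0.0234 with an estimated correlation, with Slc7a11 at 7444 ± 1808 against 38.1 ± 15.9. Of p53 targets, 13 of 26 were higher and 1 lower (13 and 1 adjusted over the list alone), adjusted p = 0.0468 with an estimated correlation. Of S phase genes, 20 of 36 were lower (23 adjusted over the list alone), adjusted p = 0.037 with an estimated correlation. limma called 6974 genes in HSC and 3430 in GMP.

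Sex-linked genes divided the mouse libraries in a way the labels do not describe. Xist, from the inactive X chromosome, was at 21.6 to 50.5 and Ddx3y, from the Y chromosome, at 687 to 1172 in the 12 in vivo libraries. In the 8 cultured libraries numbered 1 both were present (Xist 1917 to 7514, Ddx3y 434 to 1028), and in the 8 numbered 2 and the 8 numbered 3 Xist was at 9028 to 28893 and 7239 to 40084 with Ddx3y at 0 to 5.5 and 0 to 3.7. Both arms of each TNFα comparison held the same mix.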
